A study of Gallus gallus with 12 samples.

How the data were processed

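Breast muscle RNA (pectoralis major) from 24 chickens was compared on 12 two-colour microarrays. The birds carried either the QQ or the qq genotype of a quantitative trait locus for meat pH, 12 birds of each. Each array held 1 QQ bird and 1 qq bird, with QQ in the Cy5 channel on 6 arrays and in the Cy3 channel on the other 6. The arrays lay on 3 slides of 4, with 2 arrays of each dye orientation per slide. An array is named here by its orientation and replicate number, such as QQ in Cy5 replicate 1. No sex, age, pH value or sire of a bird was given.

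Per the file headers, the scanner files came from Agilent Feature Extraction and hold the mean pixel intensity of each spot and the median intensity of its local background for both channels. The deposited scanner files also hold processed intensity values, background-subtracted and dye-normalised by that software, and a log10 ratio of Cy5 over Cy3. They carry flags of 0 or 1 per spot for signal well above background, saturation and outlier pixels. The authors' table of values holds a log2 ratio per probe and array, centred near 0, and its normalisation was not stated. Compared with the scanner ratios, every column of that table ran as qq over QQ. Its values, turned to Cy5 over Cy3, differed by at most 0.02 on any array from loess-normalised mean signals with no background subtraction. The probe positions used here are those of the array file, whose build the header gives as galGal2.

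The main values started from the mean signals and background medians. Background was corrected by normexp with an offset of 50, and ratios were normalised by loess within each array, with control spots given no weight. Spots with outlier flags were set to missing and control spots were removed. A probe was kept when it was well above background in at least 6 of the 12 birds of either genotype, which left 25007 of 42034 probes. Limma 3.58.1 in R 4.3.3 fitted each probe's log2 ratio with the genotype contrast (QQ minus qq) and a dye intercept. P values were two-sided and adjusted by the Benjamini-Hochberg method over all probes tested, and a probe was called at an adjusted p under 0.05. Tables were read with data.table (version 1.17.8), and plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

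Probes were given gene symbols by transcript accession (5309 probes), gene number (3781), current symbol (885) or older symbol (94), and 31965 probes had no match. The 10069 matched probes stood for 8682 genes. Each gene was represented by its brightest probe, which gave 7209 genes tested. Unmatched probes are named by the sequence accession on the array, and the gene they measure was not assigned. Transcript features under a probe were not annotated in the files, so exon or untranslated region is not given.

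Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry. Of 24 lists, 23 with at least 5 measured members were tested; the list of W chromosome genes was used as a check on sex. The clustering of genes along chromosomes was tested by the largest number of genes with unadjusted p under 0.01 in any window of 25 consecutive tested genes, against 10000 permutations, one-sided. The design set the adjusted threshold for that test, with the unadjusted one where fewer than 5 genes were called. Gene order came from a newer assembly of the chicken genome, of which no coordinates are given.

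The comparison, filters, lists, windows and the alternatives below were, with 2 exceptions, chosen before the data were examined. So was the rule for named genes. It takes the genes with the largest change among those called with the same sign on at least 9 of 12 arrays, up to 10 per direction. If fewer than 10 are called, it adds the 10 genes with the smallest p as values. It also takes up to 4 members of each list by smallest p, ACOT9 and PRDX4, the genes of the densest window and the W-linked genes, 100 genes in all. The called probes without a gene symbol, the counts of probes by distance from ACOT9 and the probes near it were named after their values had been seen.

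The alternatives were Agilent's processed signals, no background subtraction, plain subtraction, median centring in place of loess, quantile scaling of the average intensities, no filter, a stricter filter, outlier spots kept, no dye term, 1 dye intercept per slide, slide as a random block, array weights, a separate-channel fit, the authors' table, a variance trend with robust estimation, a W-linked covariate, means of a gene's probes, other window sizes and thresholds, and each array left out in turn. A normexp fit without the lowest 0.1% of spots and a fit without probes saturated in any bird (87 of those tested) were added after the data had been seen. The fit was tested on simulated data: of 67 probes changed by a log2 ratio of 0.5, 65.7% were called, of 67 changed by 1, 95.5%, and of 66 changed by 2, 100%, with 9 unchanged probes called. All these changes were planted together, many more than the probes called in the real data. The adjusted threshold was therefore easier to pass, and these shares overstate the power of the real comparison. A simulated list shifted by 0.3 had the smallest p of the lists, and 0 others were called. The simulated probes varied independently of one another, so this did not test false calls of lists whose genes vary together.

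The median signal of the probes was 72.6 to 115 intensity units in Cy3 and 73.4 to 90.4 in Cy5 across arrays, against median backgrounds of 38 to 54 and 48 to 52. Between 48.3% and 64.5% of probes per channel were well above background. The number of arrays, 12, limits the precision of each ratio.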

Results

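RNA levels in breast muscle were measured on 12 two-colour arrays, each comparing 1 QQ bird with 1 qq bird at a locus for meat pH, so that 12 birds of each genotype were compared. The title of the series names the aim as finding genetic mechanisms behind meat pH in the chicken. Ratios are given as log2 of QQ over qq with their standard error (SE, n = 12 arrays), and a positive value means a higher probe signal in QQ birds. Signal is read here as RNA level. Sequence differences between the chromosome copies under a probe could also change its signal. Near ACOT9, on chromosome 1, the data could not tell these apart, so ratios there are differences in signal. The fit removes the dye effect, which 749 of 25007 probes had at an adjusted p under 0.05 (limma). Values and list medians of single arrays, and counts of arrays by sign, still hold it.

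ACOT9, a mitochondrial acyl-CoA thioesterase, was 2.10-fold higher in QQ birds (log2 1.07 ± 0.09, adjusted p = 3.80e-04), and higher on 12 of 12 arrays. Its probe lies on chromosome 1 at 111701241 to 111701300 (galGal2). The mean log2 level was 9.21 ± 0.32 (SD, n = 12) in QQ and 8.14 ± 0.19 in qq birds. The ratio was 1.05, 1.08 and 1.10 on the slides taken one at a time, and 1.07 with a dye intercept for each slide (adjusted p = 0.0027). Of the 7209 genes tested, ACOT9 alone passed the adjusted threshold in limma, while 709 genes had an unadjusted p under 0.05, 446 higher and 263 lower in QQ.

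In all, 12 of 25007 probes were called, 4 higher and 8 lower in QQ birds. Of these, 11 carry no gene symbol in the table used. The largest ratio among the called probes was at CR385747 (chromosome 1, 111581038 to 111581097), which was 4.89-fold higher in QQ (log2 2.29 ± 0.15, adjusted p = 2.55e-05, higher on 12 of 12 arrays). Past ACOT9, BU382605 (111708214 to 111708273) was higher by log2 0.54 ± 0.08 (adjusted p = 0.0480, 11 of 12 arrays), and BU299642 (111709151 to 111709211) by 1.03 ± 0.12 (adjusted p = 0.0089, 12 of 12 arrays). BU299642 was well above background in only 4 of 12 qq birds, so its ratio rests on dim qq signals.

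The 8 other probes were lower in QQ. BU230994 (chromosome 1, 111780742 to 111780801) was 4.80-fold higher in qq than in QQ birds (log2 -2.26 ± 0.27, adjusted p = 0.0089, lower in QQ on 12 of 12 arrays), and it was well above background in 9 of 12 QQ birds. CR390282 (111623009 to 111624478) had a log2 ratio of -0.71 ± 0.10, CR387057 (107563997 to 107564056) one of -0.76 ± 0.10, BU126270 (116659594 to 116659653) one of -1.79 ± 0.27, and TC202659 (117186110 to 117186169) one of -0.71 ± 0.11. They were lower on 11, 10, 11 and 12 of 12 arrays, with adjusted p of 0.0273, 0.0122, 0.0350 and 0.0350. Away from chromosome 1, BU418179 (chromosome 4, 39603817 to 39603876) had a log2 ratio of -0.45 ± 0.06 and was lower on 12 of 12 arrays (adjusted p = 0.0089). BU108463 (-2.27 ± 0.29, adjusted p = 0.0112) and BU106729 (-1.21 ± 0.15, adjusted p = 0.0109) were lower on 12 of 12 arrays and had no position. BU108463 gave -1.39, -2.13 and -3.29 on the 3 slides. No probe had a slide by genotype effect past the adjusted threshold in limma, and 498 had one at an unadjusted p under 0.05.

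**Figure D1:**
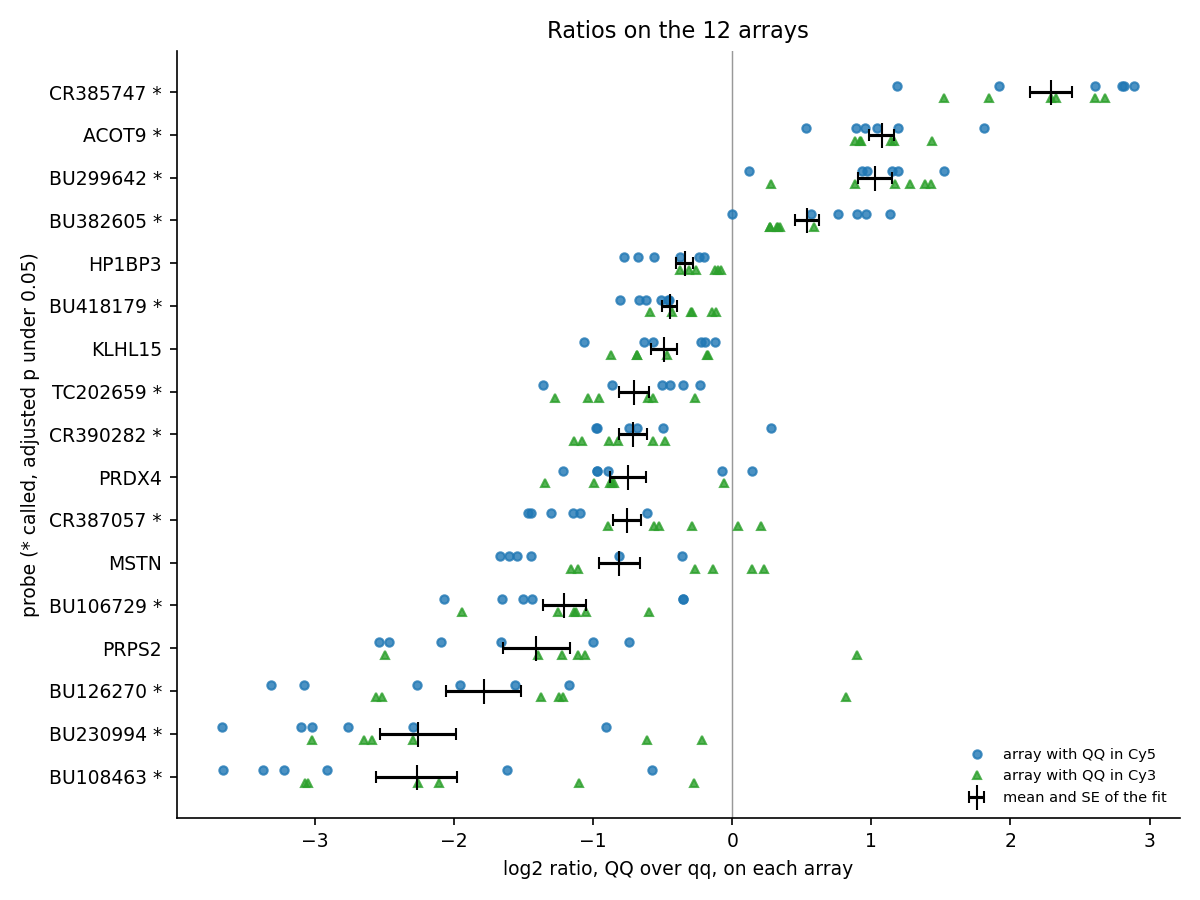
Log2 ratio of QQ over qq on each of the 12 arrays for the 12 called probes, marked with an asterisk, and the 5 genes next in order of p. Circles are arrays with QQ in Cy5, triangles arrays with QQ in Cy3, and black bars the fitted mean with its SE; ACOT9 lies between 0.53 and 1.81.

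The count of called probes depended on single arrays. It was 23 without QQ in Cy5 replicate 1, with 10 genes called, and 7 without QQ in Cy5 replicate 3, QQ in Cy5 replicate 4 or QQ in Cy3 replicate 6. With a dye intercept per slide, 14 probes and 4 genes were called. Centring the ratios on the median in place of loess gave 6 probes, 5 higher and 1 lower, and the processed signals gave 4 higher and 4 lower.

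The differences gathered on chromosome 1. Of the 10 called probes with a position, 9 lay there, all within 10 Mb of the ACOT9 probe and over 9.62 Mb in all, and 6 lay within 0.5 Mb of it. Within 10 Mb of ACOT9, 36 of 288 probes (12.5%) had an unadjusted p under 0.01, against 375 of 19222 (1.95%) on other chromosomes (Fisher's exact test, two-sided, p = 7.48e-18, odds ratio 7.18; neighbouring probes are not independent). The share was 40% of 30 probes within 0.5 Mb, 0 of 44 probes from 0.5 to 2.5 Mb, 18.9% of 74 probes from 2.5 to 5 Mb and 7.14% of 140 probes from 5 to 10 Mb. From 10 to 20 Mb it was 4.35% of 322 probes, and past 40 Mb 1.62% of 1919.

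**Figure D2:**
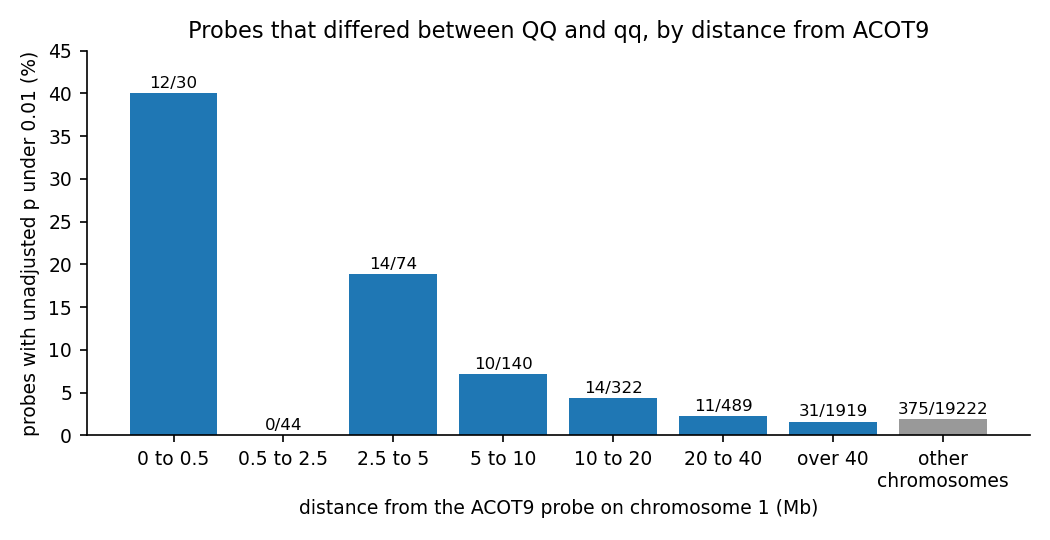
Percent of tested probes with an unadjusted p under 0.01 by distance from the ACOT9 probe along chromosome 1 (blue) and on other chromosomes (grey), with the counts above the bars. The share was 40% within 0.5 Mb and 1.95% on other chromosomes.

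**Figure D3:**
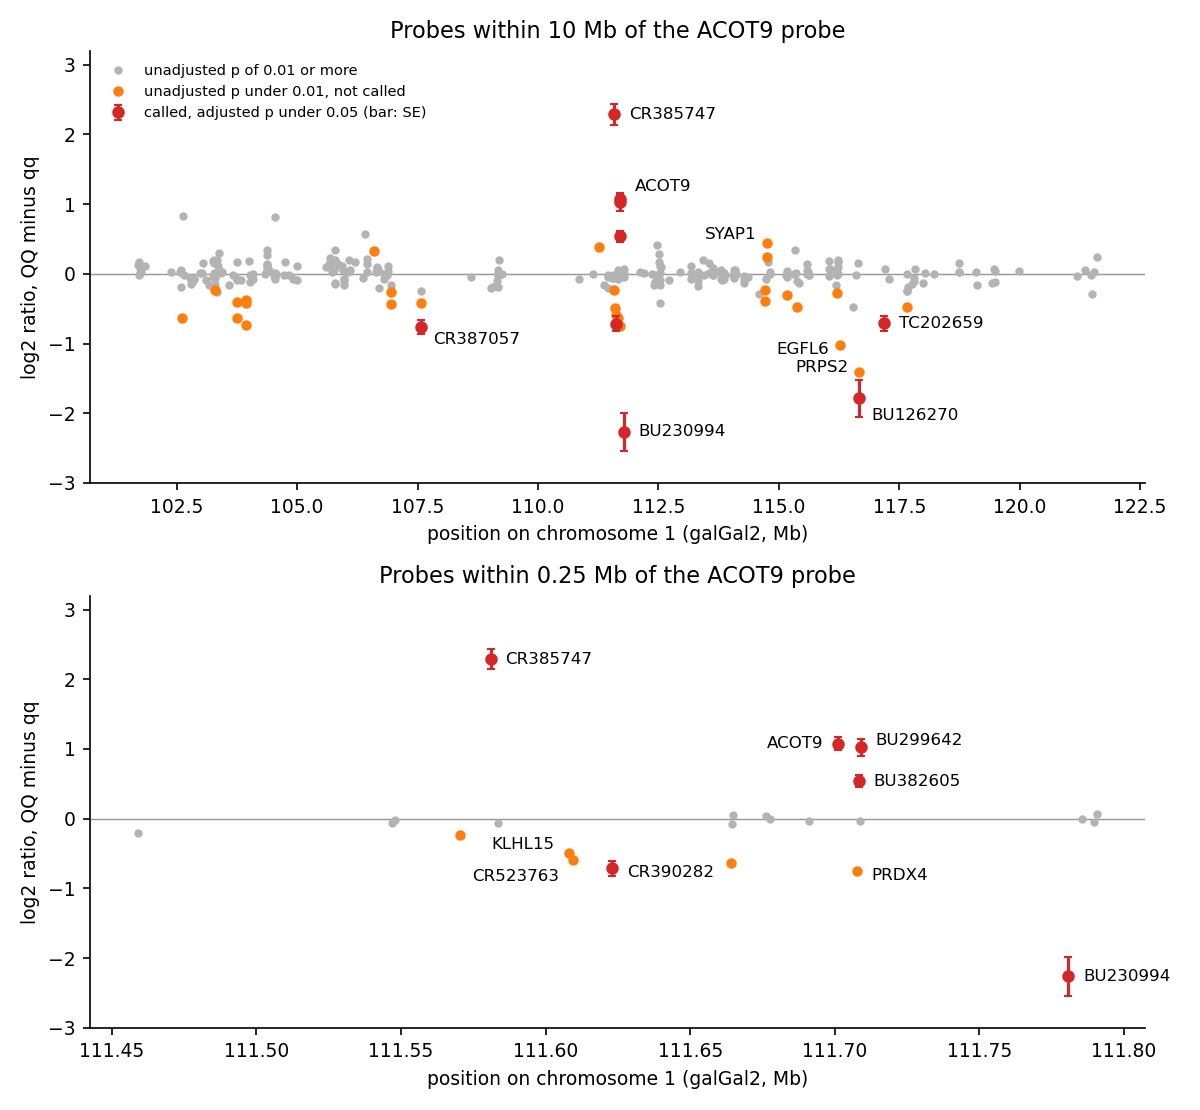
Log2 ratio of QQ over qq by galGal2 position on chromosome 1, within 10 Mb of the ACOT9 probe (top) and next to it (bottom). Red points are called probes with their SE, orange points other probes with an unadjusted p under 0.01, and grey points the rest; CR385747 stands at 2.29 and BU230994 at -2.26.

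Several named genes near ACOT9 were next in order of p and did not pass the threshold. PRDX4, a peroxiredoxin of the endoplasmic reticulum, had a log2 ratio of -0.75 ± 0.13 (adjusted p = 0.0959, lower in QQ on 11 of 12 arrays); its probe lies 6.36 kb from that of ACOT9 (111707600 to 111707659). The PRDX4 ratios on the slides were -0.42, -0.78 and -1.05, and with a dye intercept per slide it passed (adjusted p = 0.0303). It also passed with the separate-channel fit, with a W-linked covariate, and without QQ in Cy5 replicate 1 (0.0489), QQ in Cy5 replicate 2 (0.0397) or QQ in Cy3 replicate 3 (0.0358), over a range of 0.0148 to 0.391 in all alternatives. PRPS2, an enzyme that makes phosphoribosyl pyrophosphate for nucleotide synthesis, had -1.41 ± 0.24 (adjusted p = 0.0867, lower on 11 of 12 arrays). It passed with a dye intercept per slide (adjusted p = 0.0246), plain subtraction (0.0355), the separate-channel fit (0.0016), and without QQ in Cy5 replicate 1 (0.0489) or QQ in Cy3 replicate 3 (0.0063). KLHL15, an adaptor of a ubiquitin ligase, had -0.49 ± 0.09 (adjusted p = 0.142, lower on 12 of 12 arrays). EGFL6, a secreted matrix protein, had -1.02 ± 0.20 (adjusted p = 0.233, but 0.0489 without QQ in Cy5 replicate 1), and SYAP1 had 0.44 ± 0.09 (adjusted p = 0.256, higher on 12 of 12 arrays, but 0.0162 with the separate-channel fit).

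The list of genes around ACOT9 and PRDX4 was drawn up from what is known of the study, so it is not independent evidence. Of its 21 measured members, 10 had ratios above 0 and 11 below, 1 was called over all probes (ACOT9) and 3 were called when adjusted over the list alone (ACOT9, PRDX4 and KLHL15). Fry's mixed test for a change in either direction gave p = 1.63e-07, and when the arrays were regrouped by permutation only the real grouping of 100 gave a value as small. Fry's mixed value was smaller still for the fatty acid oxidation list, where ACOT9 alone was called. It was larger for the antioxidant list, which holds PRDX4 and not ACOT9. ACOT9 alone may therefore be enough to give the segment's value, which does not show a change across the segment. Against other genes, camera gave no call for the list around ACOT9 and PRDX4 (median log2 ratio -0.05, but 0.10 with median centring, adjusted p = 0.0860, and adjusted p = 0.596 with an estimated correlation). Without QQ in Cy3 replicate 1 or QQ in Cy5 replicate 6, camera placed it lower (adjusted p = 0.0386 and 0.0071). In the window test, at most 5 of 25 consecutive genes had an unadjusted p under 0.01, which permutation did not separate from a random order (p = 0.188, one-sided). Of 18 windows with that count, 7 held KLHL15, ACOT9, PRDX4, RBBP7 and SYAP1. Another 10 held RBBP7, SYAP1, TRAPPC2, EGFL6 and PRPS2, without ACOT9 or PRDX4, and 1 held ACOT9, PRDX4, RBBP7, SYAP1 and TRAPPC2. Windows of 51 genes held 8 such genes (permutation p = 0.0089).

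Away from the region, MSTN, an inhibitor of muscle growth, had a log2 ratio of -0.81 ± 0.15 (adjusted p = 0.133, lower in QQ on 10 of 12 arrays). It passed the adjusted threshold without QQ in Cy5 replicate 1 (adjusted p = 0.0390). HP1BP3, a chromatin protein, had -0.34 ± 0.06 (adjusted p = 0.115, but 0.0237 with array weights; 12 of 12 arrays lower). ENPP4 had 0.63 ± 0.12 (adjusted p = 0.196, but 0.0342 with the separate-channel fit). PPP2R3A, a phosphatase subunit, had 0.41 ± 0.08 (adjusted p = 0.256) and LSS, the lanosterol synthase of sterol synthesis, -0.51 ± 0.10 (adjusted p = 0.248). Both passed without QQ in Cy5 replicate 1 (0.0258 and 0.0323), and LSS with the separate-channel fit (0.0417).

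Camera called 7 of 23 gene lists with its preset correlation. None was called with an estimated correlation (limma, adjusted p = 0.543 for each of the 7), and none had an unadjusted p under 0.05 that way. With the preset correlation, interferon-stimulated genes were placed higher in QQ, with a median of 0.28 (adjusted p = 5.17e-04, and adjusted p = 0.543 with an estimated correlation). Of 16 members, 14 had ratios above 0, 8 of them with an unadjusted p under 0.05. The estimated correlation between members was 0.28, so these counts are not separate evidence. Fry's directional test gave an adjusted p of 0.50 for this list. None of its members was called over all probes and 0 were called when adjusted over the list alone. MX1, an antiviral GTPase, had 0.82 ± 0.29 (-0.59 to 2.63 over the arrays), OASL 0.36 ± 0.12, IRF9, a transcription factor of interferon signalling, 0.29 ± 0.11, and PARP12 0.27 ± 0.09. The list's median was above 0 on 10 of 12 arrays, at 0.32, 0.21 and 0.26 on the 3 slides, and reached 1.10 on QQ in Cy3 replicate 1. Without that array it was 0.22 (adjusted p = 0.0042).

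Leukocyte markers were also placed higher in QQ by camera with the preset correlation, with 20 of 23 members above 0, a median of 0.15 (above 0 on 9 of 12 arrays) and an adjusted p of 0.0037 (adjusted p = 0.543 with an estimated correlation). The size depended on the scaling: the median was 0.34 with the processed signals, 0.29 with plain subtraction and 0.26 with median centring. The median of all genes was 0.09, 0.03 and 0.08 in these, against 0.02 in the main values. C1QC, a complement protein of macrophages, had 0.36 ± 0.14, CTSS, a lysosomal protease, 0.38 ± 0.17, and SPI1, a myeloid transcription factor, 0.14 ± 0.06. The joining chain of antibodies, JCHAIN, was well above background in 11 of 12 QQ and only 4 of 12 qq birds, so its ratio is not given. No member was called over all probes or adjusted over the list alone.

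Camera placed markers of fibroblasts and extracellular matrix lower in QQ, with 17 of 19 members below 0, a median of -0.16 and an adjusted p of 0.0017 (adjusted p = 0.543 with an estimated correlation). The arrays were divided, with the median below 0 on 6 and above 0 on 6 of 12, from -1.49 on QQ in Cy5 replicate 3 to 0.47 on QQ in Cy3 replicate 3. COL6A2 had -0.50 ± 0.19, COL14A1 -0.41 ± 0.18 and COL6A1 -0.30 ± 0.16, collagens of the muscle matrix, and FBN2 -0.13 ± 0.09. Red blood cell markers were placed lower, with 5 of 6 members below 0, a median of -0.26 (below 0 on 8 of 12 arrays) and an adjusted p of 0.0369 (adjusted p = 0.543 with an estimated correlation); the globins HBBA and HBA1 had -0.64 ± 0.28 and -0.55 ± 0.30, RHAG -0.22 ± 0.11, and CA2 -0.30 ± 0.46. The matrix call was lost with array weights (adjusted p = 0.193), where the median was -0.03. The red cell call was lost without any of QQ in Cy5 replicates 1, 4 and 6 or QQ in Cy3 replicates 1 and 2 (adjusted p = 0.0762, 0.0633, 0.197, 0.0818 and 0.156), and with plain subtraction (0.0615) or the authors' table (0.0508). The red cell median stayed below 0 in these fits, at -0.32, -0.32, -0.25, -0.22, -0.20, -0.44 and -0.31 in the same order.

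Camera placed 3 more lists lower in QQ, by small amounts that depended on the scaling. For the tricarboxylic acid cycle and pyruvate entry, 12 of 17 members were below 0, with a median of -0.09 (0.07 with median centring), below 0 on 10 of 12 arrays, and an adjusted p of 0.0265 (adjusted p = 0.543 with an estimated correlation). SDHA had -0.28 ± 0.11, MDH1 -0.28 ± 0.09, DLAT -0.26 ± 0.10 and IDH3A -0.25 ± 0.12, enzymes of the cycle or of entry into it. For fast muscle fibre, 13 of 15 members were below 0, with a median of -0.09 (0.10 with median centring) and an adjusted p of 0.0318 (adjusted p = 0.543 with an estimated correlation). The slide medians were 0.03, -0.02 and -0.20, and the median was below 0 on 7 of 12 arrays. The array medians followed the dye: they ran from -0.19 to 0.63 with QQ in Cy5 and from -0.64 to -0.05 with QQ in Cy3. RYR3, a calcium release channel, had -0.23 ± 0.12 and CASQ2, a calcium store protein, -0.18 ± 0.10 (0.02 with median centring), while PVALB, a calcium buffer, had 0.41 ± 0.31. For heat shock and protein folding, 18 of 30 members were below 0, with a median of -0.04 (0.07 with median centring), below 0 on 7 of 12 arrays, and an adjusted p of 0.0265 (adjusted p = 0.543 with an estimated correlation), with the chaperone genes DNAJA1 at -0.36 ± 0.10, SERPINH1 at -0.41 ± 0.19 and DNAJB9 at -0.23 ± 0.10. With median centring in place of loess these 3 calls were lost, and the median of all genes was 0.08 against 0.02 in the main values. With the processed signals the tricarboxylic acid cycle and fast fibre lists lost their call (adjusted p = 0.0937 and 0.162), with medians of -0.03 and 0.00. The call of the tricarboxylic acid cycle was also lost with plain subtraction and without QQ in Cy5 replicate 2 or 5 (adjusted p = 0.0518, 0.0653 and 0.0715), with medians of -0.11, -0.06 and -0.07. The fast fibre call was lost in 11 of 30 alternatives, among them plain subtraction, no filter, no dye term, array weights and the authors' table (0.0682, 0.104, 0.0968, 0.0561 and 0.0508). In these the median stayed near the main value, at -0.09, -0.08, -0.09, -0.08 and -0.08. The fast fibre call was also lost without QQ in Cy5 replicate 1 or 6 or QQ in Cy3 replicate 2 or 5 (0.0532, 0.426, 0.0777 and 0.0714), with medians of -0.09, -0.03, -0.07 and -0.06. The heat shock call was lost without QQ in Cy5 replicate 3, 4 or 5 or QQ in Cy3 replicate 4 (0.110, 0.0520, 0.0715 and 0.0917), with medians of -0.02, -0.05, -0.02 and -0.005. No member of the 3 lists was called over all probes or adjusted over the list alone.

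**Figure D4:**
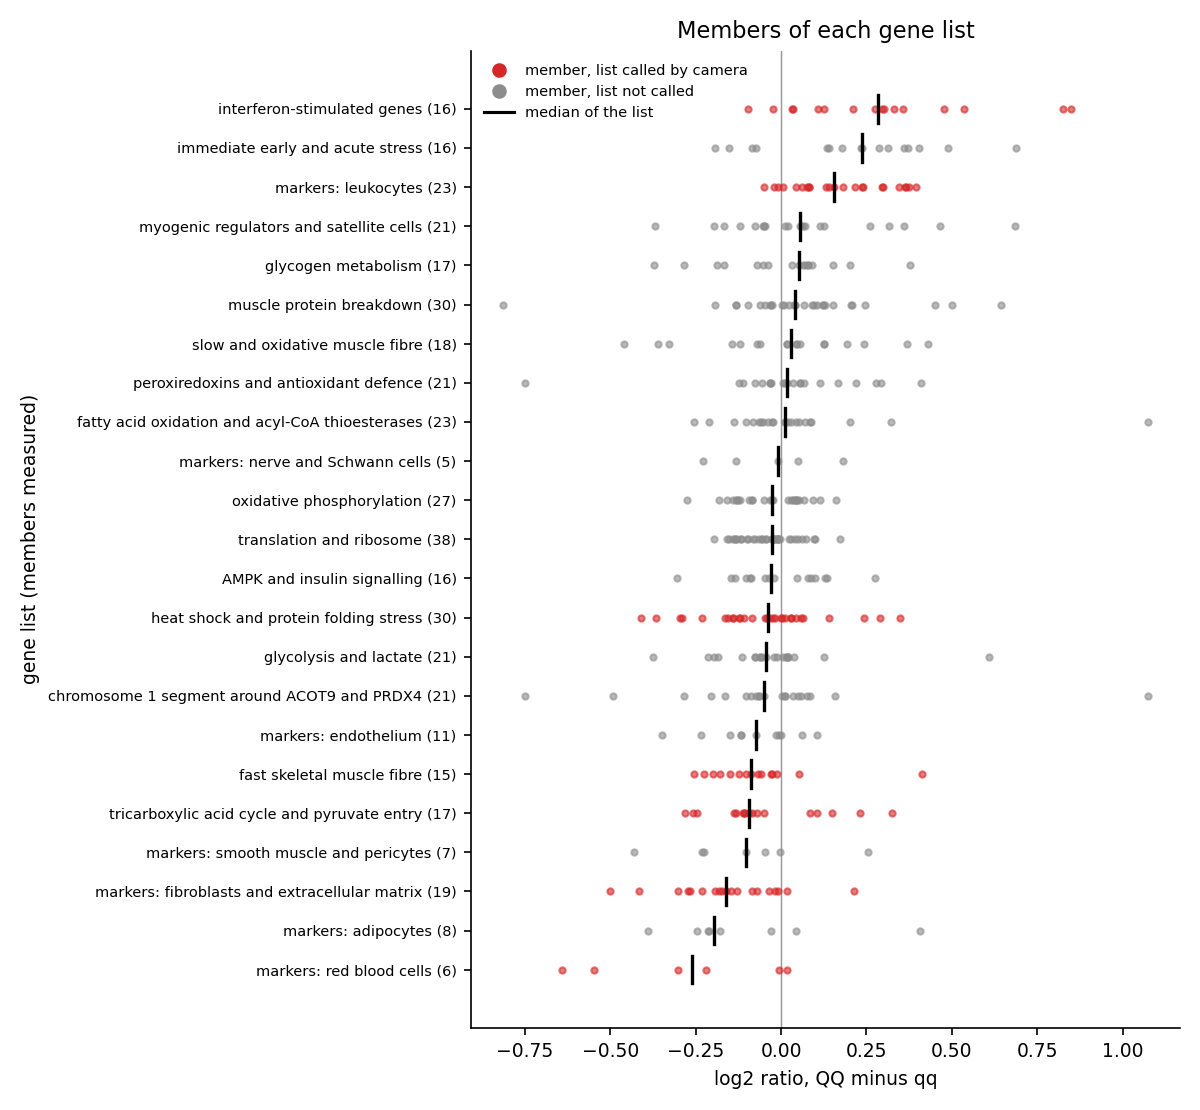
Log2 ratio of QQ over qq of each measured member (points) and the median (black line) of the 23 gene lists, with the number of members in brackets; red lists were called by camera with the preset correlation and none with an estimated one. The interferon list has the highest median, 0.28, and red blood cell markers the lowest, -0.26.

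The lists closest to muscle pH were not called. Glycogen metabolism had 10 of 17 members above 0 (median 0.05, mean 0.00, adjusted p = 0.677), with the glycogen enzymes PHKB at -0.29 ± 0.14 and GSK3A at -0.19 ± 0.10, and PPP1R3D, which brings a phosphatase to glycogen, at 0.38 ± 0.27. Glycolysis and lactate had 13 of 21 below 0 (median -0.04, but 0.08 with median centring, adjusted p = 0.102), with HK1, a hexokinase, at -0.12 ± 0.09 (0.08 with median centring) and PFKFB3, a regulator of glycolysis, at 0.61 ± 0.22 (well above background in 9 of 12 qq birds). The probes of PGM1, GPI, LDHA and UCP3 were saturated in some birds of both genotypes, so their ratios are not given. Of 21 glycolysis genes 8 were so in at least 1 bird, and without all saturated probes the median of that list was -0.01 (adjusted p = 0.822). Signalling through AMPK and insulin had a median of -0.03 (0.08 with median centring, 16 members, adjusted p = 0.866), with PRKAA1, a catalytic subunit of AMPK, at 0.27 ± 0.09. Oxidative phosphorylation had 15 of 27 below 0 (median -0.03, but 0.15 with median centring, adjusted p = 0.102). Fatty acid oxidation and thioesterases, the other list that holds ACOT9, had a median of 0.01 (23 members, adjusted p = 0.866), with PPARD, a regulator of fat oxidation, at 0.32 ± 0.11; only ACOT9 was called when adjusted over the list alone. Antioxidant defence had a median of 0.02 (21 members, adjusted p = 0.866), with catalase (CAT) at 0.41 ± 0.14 and HMOX1, a heme-degrading enzyme, at 0.29 ± 0.12, and PRDX4 was called when adjusted over the list alone (adjusted p = 0.0014).

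Slow and oxidative fibre had a median of 0.03 (18 members, adjusted p = 0.866), with the calcium pump ATP2A2 at -0.33 ± 0.11 and the slow myosin light chain MYL2 at 0.19 ± 0.09. Muscle protein breakdown had 20 of 30 members above 0 (median 0.04, adjusted p = 0.578), and 3 were called when adjusted over the list alone: MSTN, CTSV, a cathepsin, at 0.64 ± 0.15, and FBXO30, a ubiquitin ligase subunit, at 0.21 ± 0.05 (adjusted p = 0.0032, 0.0113 and 0.0121). Over all probes their adjusted p was 0.133, 0.311 and 0.343. Adjustment over a list alone takes no account of the number of lists, so some such calls can arise by chance. No gene called that way in this paragraph was called over all probes. FBXO30 was well above background in only 8 of 12 qq birds. Immediate early and stress genes had 12 of 16 above 0 (median 0.24, adjusted p = 0.0717), with BTG2, an antiproliferative factor, at 0.69 ± 0.25 and the transcription factor CEBPB at 0.49 ± 0.13, called when adjusted over the list alone (adjusted p = 0.0462, but 0.425 over all probes). That list passed without QQ in Cy3 replicate 1 or 5 or QQ in Cy5 replicate 2 or 3 (adjusted p = 0.0209, 0.0488, 0.0383 and 0.0052). It also passed with slide intercepts, no background subtraction, the strict filter, array weights and the trimmed normexp fit (0.0495, 0.0494, 0.0319, 0.0148 and 0.0481), 9 of 30 alternatives in all. Ribosome and translation genes had 29 of 38 below 0 (median -0.03, but 0.14 with median centring, adjusted p = 0.0860), with slide medians of 0.18, 0.04 and -0.38. Myogenic regulators had a median of 0.05 (21 members, adjusted p = 0.677), with MYOD1, a muscle transcription factor, at 0.46 ± 0.23 (saturated in 1 QQ bird) and IGFBP5 at -0.37 ± 0.10, called when adjusted over the list alone (adjusted p = 0.0483). Of the other cell types, adipocyte markers had a median of -0.20 (8 members, adjusted p = 0.174), endothelium -0.07 (0.02 with median centring, 11 members, adjusted p = 0.0847), smooth muscle and pericytes -0.10 (7 members, adjusted p = 0.456) and nerve -0.01 (5 members, adjusted p = 0.784). PDGFRB, a receptor of pericytes, had 0.25 ± 0.07 and was called when adjusted over the list alone (adjusted p = 0.0281). Glycogen, antioxidant and slow fibre lists had medians and means above 0 while camera placed them lower, where the mean of all genes was 0.03. In the glycogen, glycolysis, AMPK, oxidative phosphorylation, slow fibre, ribosome, adipocyte, endothelium and nerve lists 0 members were called over all probes and 0 when adjusted over the list alone.

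Some alternatives brought calls to lists that had none. Oxidative phosphorylation and ribosome genes were lower in QQ with the W-linked covariate (adjusted p = 5.29e-06 for both), with array weights (0.0499 and 0.0243), without QQ in Cy5 replicate 2 (7.10e-05 and 8.37e-06) or QQ in Cy3 replicate 4 (0.0031 and 0.0012), and ribosome genes without QQ in Cy5 replicate 1 (0.0441). Their medians, -0.03 for both in the main values, were -0.11 and -0.13, -0.06 and -0.05, -0.12 and -0.15, and -0.08 and -0.11 in that order, and -0.07 for ribosome genes in the last. On QQ in Cy5 replicate 2 alone, with the dye effect still in them, their medians were 1.29 and 1.64. On QQ in Cy3 replicate 2 they were -0.63 and -0.79. Glycolysis was lower without QQ in Cy3 replicate 1 (0.0209) or with the strict filter (0.0319). Endothelium was lower without QQ in Cy5 replicate 1 or QQ in Cy3 replicate 1, 3 or 5 (0.0433, 0.0222, 0.0323 and 0.0488).

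The sex of the birds could not be settled. HINTW, carried by the W chromosome of hens, was well above background in 12 of 12 birds of each genotype, with a log2 ratio of 0.00 ± 0.13 at its brighter probe and 0.16 ± 0.13 at the other. At the brighter probe the lowest log2 level of a bird was 14.8 in QQ and 14.6 in qq, against a mean of 15.3 in each. FET1 had -0.43 ± 0.27 (adjusted p = 0.743). On QQ in Cy5 replicate 2 FET1 was at -3.20 while the brighter HINTW probe was at 1.09, so the 2 genes went apart, and on QQ in Cy3 replicate 3 they were at -1.42 and -0.32.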

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

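The tests by splits of the arrays and the tests of explanations in this part were chosen after the results had been seen. Splits are regroupings of the 12 arrays into 6 and 6, of which 100 of the 462 possible were used, the real one included.

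The called probes were more than regrouping gave: 1 of 100 splits, the real one, called 12, and the highest of the others called 1 (median 0). This argues against a random grouping of the arrays, but 100 splits cannot exclude chance. For genes, 2 of 100 splits called 1 or more, with a highest other of 1, and for the segment list the real value of 6.79 (minus log10 of fry's mixed p) was reached by 1 of 100 splits, against a highest other of 1.54. The segment value may rest on ACOT9 alone, since fry's mixed value was smaller still for the fatty acid oxidation list, where only ACOT9 was called. Its list was drawn up from what is known of the study, which favours the real grouping in advance. The splits are therefore no separate support for the segment. The splits did not argue against chance for the gene lists, where 9 of 100 splits called at least 7 and the highest other called 9 (median 4), nor for the window test, where 8 of 100 splits held at least 5 genes and the highest other held 7 (median 3).

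The gathering of differences on chromosome 1 around ACOT9 was seen in 1 of 100 splits, with 36 probes of unadjusted p under 0.01 within 10 Mb against a highest other of 14 (median 2). The region was picked for its differences on the real grouping, which favours that grouping in advance, so this comparison is no separate support. RNA differences of genes linked to the genotype and sequence differences between the chromosome copies under the probes could both give ratios that gather there. The higher share near ACOT9 (Fisher's exact p = 7.48e-18) is the pattern itself and does not tell them apart. Of 77 named genes within 10 Mb, 4 had more than 1 tested probe, and 0 of these had a p under 0.01, so no named gene could be read on separate probes. Neighbouring probes of the same orientation were mixed. BU476093 (-37.2 kb from ACOT9) had -0.63, while TC209930 (-36.9 kb) had -0.08 and APOO (-36.4 kb) 0.05. KLHL15 (-93.0 kb) and CR523763 (-91.7 kb) were alike, at -0.49 and -0.59. The unnamed probes were not assigned to genes, so these values do not decide between the explanations. CR385747 and BU230994, with log2 ratios of 2.29 and -2.26, would be the first to check by another assay.

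PRDX4 had a ratio near 0 on 3 of 12 arrays, QQ in Cy5 replicate 1 (-0.08), QQ in Cy5 replicate 2 (0.14) and QQ in Cy3 replicate 3 (-0.06), while on the other 9 it was lower in QQ by at least 0.85. Weak ratios on those arrays are argued against by ACOT9, whose lowest ratio was 0.53, on QQ in Cy5 replicate 1; with normexp fitted without the lowest 0.1% of spots that array gave 0.94 for ACOT9 and still -0.02 for PRDX4. Birds of the other genotype on those arrays are argued against by CR385747, whose lowest ratio was 1.18. Birds that carry another chromosome copy between the probes may account for it, and this stays open: 2 of the 3 arrays were also among the 3 with the smallest ratios of BU230994 (exact one-sided p = 0.127), and 2 of 3 for BU108463, too few to decide, and on QQ in Cy5 replicate 1 the trimmed fit moved BU230994 from -0.91 to -2.07, so its small ratio there came mainly from compression (BU108463 stayed at -0.55). On QQ in Cy3 replicate 3, BU230994 and BU108463 were at -0.21 and -0.27, and CR387057, EGFL6, BU126270 and PRPS2 were above 0 (0.21, 0.24, 0.82 and 0.90), while ACOT9 and CR385747 kept 0.89 and 2.33. Probes on both sides of PRDX4 bear on this too. ACOT9, BU382605 and BU299642 were at 1.81, 0.76 and 1.52 on QQ in Cy5 replicate 2, and at 0.89, 0.27 and 1.17 on QQ in Cy3 replicate 3. On these arrays another copy at PRDX4 would have to end before those probes on each side. On QQ in Cy5 replicate 1 the trimmed fit gave 0.94, -0.006 and 0.60.

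Among arrays, 2 of 10 tests of 6 arrays of an orientation found a value far from the others, where chance gives about 1 in 20. The interquartile range of log2 ratios was 0.0537 on QQ in Cy5 replicate 1, against 0.304 to 0.423 on the other 5. In its Cy3 channel the background mean of the normexp fit was -329 with all spots and -8.83 without the lowest 0.1%, which brought the interquartile range to 0.277. A smaller shift of the same kind, not flagged by these tests, was seen on QQ in Cy3 replicate 5. Its Cy3 background mean was -89.6 with all spots and -11.7 in the trimmed fit, and its interquartile range 0.219 and 0.306. BU106729 moved from -1.14 to -1.57 there. The share of probes well above background in Cy3 was 64.5% on QQ in Cy3 replicate 2, against 59.0% to 60.1% on the others.

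For genes and called probes, 15 of 222 such tests found a value far from the other arrays of the same orientation, where about 1 in 20 is given by chance. On QQ in Cy5 replicate 6 the log2 ratio was -1.07 for GSK3A, -0.70 for CTSB and -1.93 for ACTG2. On QQ in Cy5 replicate 3 it was 2.03 for MYL10 (well above background in 6 of 12 QQ and 2 of 12 qq birds) and -2.12 for FABP4, and on QQ in Cy5 replicate 2 it was -3.20 for FET1. On QQ in Cy3 replicate 1 it was -2.08 for EGFL6, -1.31 for DLAT, 1.19 for ACAA2 and 1.20 for OASL. On QQ in Cy3 replicate 4 it was 0.86 for RPL39L, 2.11 for C1QC and 0.76 for HINTW. MYF5 had -0.029 on QQ in Cy3 replicate 2, and BU382605 had 0.58 on QQ in Cy3 replicate 5.

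The spike-in control spots, used in no comparison, gave signal on every array. Their lowest median over background was 815 intensity units, against a median signal of 41.0 to 72.3 at the dark corner spots, and all 320 spots of 10 probes were well above background in both channels. The spike-in ratios spanned 5.37 on QQ in Cy5 replicate 1 and 5.48 to 6.31 on the other arrays (log2).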

How the results depend on the processing

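Of the alternatives, 2 were chosen after seeing the data. Normexp fitted without the lowest 0.1% of spots gave 15 probes (4 higher, 11 lower), 1 gene and 8 lists, with all 12 main probes among them. Without saturated probes there were 12 probes, 1 gene and 7 lists, all as before. ACOT9 passed in all 18 settings and all 12 fits with an array left out, with log2 ratios of 0.97 to 1.45 and adjusted p up to 0.0027. No called gene or probe changed sign, and camera kept its direction for the called lists, but with median centring the medians of the tricarboxylic acid cycle, fast fibre and heat shock lists turned above 0 (0.07, 0.10 and 0.07). Of 3283 values of named genes under alternatives and on single slides (no test), 3252 were counted as the same, 19 passed where the main value did not and 12 moved. For a gene not called, the same meant a shift under 1 SD of its single-array ratios. That SD still holds the dye effect, and a change of sign within it counted as the same, so this is a loose rule. Of 688 list values 630 were counted as the same, 29 lost and 26 gained a call. For a list not called, the limit was 1 SD of its members' ratios. The interferon and leukocyte lists kept their call in 30 of 30 settings with the preset correlation, the matrix list in 29, the tricarboxylic acid cycle and heat shock lists in 25, the red cell list in 22 of 29 and fast fibre in 19. With median centring, 11 of 100 named genes had another sign, none of them called. The main probes still called ranged from 5 to 12 over the settings. Probes called were 6 with median centring, 28 with the separate-channel fit (8 higher, 20 lower) and 502 at an unadjusted p under 0.01. Genes called were 2 with plain subtraction, median centring, array weights or the W-linked covariate, 4 with slide intercepts and 8 with the separate-channel fit. Lists called were 4 with plain subtraction or median centring, and 0 with an estimated correlation. The window test passed with no background subtraction (permutation p = 0.0134), plain subtraction (0.0033), the strict filter (0.00070), no dye term (0.050, just under the threshold), array weights (0.0057), the separate-channel fit (0.0161), the authors' table (0.0136), the W-linked covariate (0.0354) and windows of 51 genes (0.0089). It also passed without QQ in Cy5 replicate 1 (0.0487) or 6 (0.0071) or QQ in Cy3 replicate 1 (0.0271) or 5 (0.0356). With an array left out, probes ranged from 7 to 23, genes from 1 to 10, lists from 5 to 10, the segment's mixed p from 1.06e-08 to 2.11e-05 (1.59e-11 to 4.72e-04 over the other settings) and the window p from 0.0071 to 0.71. Fry was not run with the separate-channel fit. The cause was not tested for any of these, apart from the thresholds and window sizes themselves. Low signal limited BU299642, BU230994 and BU106729, and also JCHAIN, MYL10, FBXO30, PFKFB3 and PDGFRB, which were near background in 2 or more birds of the lower genotype.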

Other observations

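The hypothesis test in this part was chosen after the results had been seen.

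BU382605 and BU299642 lie 6.97 and 7.91 kb past the ACOT9 probe, on its orientation, and both were higher in QQ as ACOT9 was. A candidate explanation is 1 transcript that reaches past the ACOT9 probe. If so, they should vary with ACOT9 across arrays after the genotype and dye effects are removed. Over 12 arrays, with normexp fitted without the lowest 0.1% of spots, Pearson's r with ACOT9 was 0.54 for BU299642 (permutation p = 0.0787, adjusted 0.157 over the 2 relations) and 0.16 for BU382605 (permutation p = 0.582). Spearman's rho was 0.47 (permutation p = 0.128) and 0.01 (permutation p = 0.975). Without the 2 arrays farthest from the median of ACOT9, r was 0.45 and 0.17. BU299642 was well above background in only 4 of 12 qq birds, so its r rests in part on dim signals. The smaller r, 0.164, leaves the explanation undecided. PRDX4 (-0.75 ± 0.13) and TC192701 (111708598 to 111708657, -0.04 ± 0.07), whose probes lie between on the reverse orientation, did not follow ACOT9.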
